A study of Homo sapiens with 25 samples.

How the data were processed

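RNA from aneurysmal ascending aortic wall was measured on Affymetrix human gene expression arrays, which read each gene with 1 or more groups of short oligonucleotides called probe sets. The series holds 25 arrays, 1 per patient, from 13 patients with a bicuspid aortic valve (BAV) and 12 with a tricuspid aortic valve (TAV). Groups were taken from the sample labels, and arrays were numbered within each group in the order of deposit, so a number pairs no BAV array with a TAV array. The labels used here give no scan day or processing batch, so no batch could be tested. Age, sex and other patient details were not used as covariates.

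The values deposited by the authors are probe-set intensities on a linear scale. The probe-set summary, background treatment and normalization that made them are not given in the sources used here. The design text names a linear model and GeneSpring as methods of analysis, not as the origin of these values. The table held 22215 probe sets and 25 columns. Values ran from 57.9 to 35085, and array medians from 208 to 223. No value lay near 0, so a background level remained in the values and fold differences are understated, most of all for dim genes. The array 75th percentiles spanned 0.063 on the log2 scale, within the 0.5 set as the limit for keeping the deposited normalization. The highest correlation between any 2 arrays was 0.987, and no array was treated as a duplicate. For arrays, precision is limited by their number, since no read depth exists.

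Intensities were analysed as log2(intensity + 16), and every log2 difference and fold below is on that scale. Gene symbols came from a table of the platform's annotation. Of the probe sets, 19065 had 1 gene symbol, 1043 had several and 2107 had none, and only those with 1 symbol were named. Entrez identifiers of 19053 probe sets were found in the RefSeq gene table, and 0 symbols needed updating. The probe set with the highest mean stood for its gene, which gave 11939 genes. Genes whose mean lay below the 40th percentile of probe sets (log2 7.73, an intensity of 197) were left out, and 8344 genes were tested. Affymetrix control probe sets were not in the table used here (0 found), so the planned ratios of GAPDH and ACTB control probes, which track RNA degradation, were not computed. Sex-linked genes that would reveal a patient's sex were left out.

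The comparison was BAV against TAV in limma 3.58.1 under R 4.3.3, with lmFit and eBayes, 2-sided moderated tests and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05. Confidence intervals are at 95%. A set of 46 gene lists covered cell types, extracellular matrix, signalling and stress responses. It held 1176 genes, of which 1032 had a probe set. The 45 lists with at least 5 tested genes were compared with all other genes by camera with a preset correlation between genes of 0.01, and again with the correlation estimated per list and with fry, a rotation test of each list by itself. The list of mesothelial and epithelial markers had 3 tested genes and was not tested. The mean log2 level of a list in each array was compared between groups by a 2-sided permutation test with 100000 resamples, in which the patient is the unit. SPP1 and TNC were tested per probe set in the same way, as were array medians, 75th percentiles and the first 3 principal components. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for permutations and plots, with the random seed 20. Ratios of SDs between groups, taken on deviations from group means, were tested by permutation with the same number of resamples. So were correlations across all arrays, which were taken without regard to group.

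The tests, the gene lists, most of the other settings tried and the naming rule were fixed before the data were examined. The rule took the 12 genes of smallest p in each direction, whether or not they passed, up to 4 genes of smallest p in each list discussed, and SPP1 and TNC. Not every gene that the rule takes is reported here. SPP1 and TNC were named in advance because the group that made the series is known to have written on them in these samples, so they are not independent of these data. Probe sets whose suffix marks possible cross-hybridization stood for 47 of the 94 genes taken by the rule, among them every immunoglobulin gene named. Of the 51 other probe sets above the filter for 29 of these genes, 2 had the opposite sign, for LOXL2 and MFNG. That count is of signs alone, and some of the others lay near 0, as for COL1A1, PLAUR and ENG.

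The limma step was tested on simulated data of 8344 genes with the real group sizes, for BAV against TAV. Independent genes were given 1 SD per gene, pooled over both groups. Differences of all sizes were added together, which eases the adjusted threshold for the smaller ones. Recovery is therefore not the power of the real comparison, where genes such as SPP1 differ in spread between groups. With independent genes it recovered 58% of 50 genes that differed by 0.25 log2, 96% at 0.5 and 100% at 1 and 1.5, with 8 false calls among 8144 genes. With differences added to the real arrays under 1 shuffle of the labels it recovered 58%, 98%, 100% and 100%, with 0 false calls, though another shuffle of the real arrays with nothing added gave 171. In a simulation of lists with independent genes, 4 of 4 lists shifted by 0.3 log2 were recovered and 0 of the other 41 were called. That count does not describe false calls on the real arrays, whose genes are correlated: there camera with its preset correlation called as many as 24 lists when the group labels were shuffled, and 46 of 100 splits, the real one included, gave at least the 13 lists of the real groups.

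Alternatives covered quantile normalization, centring on array medians, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, the mean of all probe sets per gene, all probe sets singly, array weights, a linear model without moderation, eBayes with trend and robust settings, a rank-sum test, thresholds of 0.1 and 0.01, a 1.5-fold requirement, lists without shared members, and each of the 25 arrays left out in turn. Added after the data were seen were subtraction of each array's 2nd percentile with a floor of 16, the removal of arrays with a limma weight under 0.5, and the first principal component as a covariate.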

Results

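Gene expression was measured in the aneurysmal wall of the ascending aorta from 25 patients, 13 with a bicuspid aortic valve (BAV, a valve with a pair of cusps instead of the usual 3) and 12 with a tricuspid aortic valve (TAV). Each patient gave 1 array. The comparison asks whether aneurysms that form beside the different valves carry different transcripts. The arrays lay on a common scale, with median intensities from 208 to 223. ACTA2, the smooth muscle actin of the aortic media, had a mean of 13.25 ± 0.42 (SD, n = 13) in BAV and 12.97 ± 0.43 (n = 12) in TAV in log2 units.

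SPP1, which encodes osteopontin, a secreted phosphoprotein made by macrophages and by cells of calcifying tissue, was lower in BAV than in TAV. Its log2 level was 7.98 ± 0.39 (SD, n = 13) in BAV and 9.23 ± 1.39 (n = 12) in TAV, a difference of -1.26 (95% confidence interval -2.04 to -0.47) or 2.39-fold. TNC, which encodes the matrix glycoprotein tenascin C, was at 7.68 ± 0.25 in BAV and 8.51 ± 0.89 in TAV, a difference of -0.83 (-1.33 to -0.32) or 1.77-fold. The BAV mean of TNC lies below the filter on dim genes (log2 7.73), where remaining background shrinks differences, and with each array's 2nd percentile subtracted, a setting added after the data were seen, its difference was -1.40. The other probe set of TNC, with means of 7.06 and 7.50 below that filter in both groups, gave a difference of -0.44. The probe set of SPP1 carries a suffix that marks possible cross-hybridization. All 13 BAV arrays lay below the TAV mean for both genes, while 5 of the 12 TAV arrays lay above the highest BAV array for SPP1 and 6 for TNC. Most TAV arrays lay below the TAV means too, since a few high TAV arrays raised them.

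Taken singly, both genes passed a 2-sided permutation test. The p was 0.00277 for SPP1 (adjusted p = 0.00277 over the 3 probe sets of both genes), 0.00092 for TNC (adjusted p = 0.00138) and 1e-04 for its other, dimmer probe set (adjusted p = 0.0003). In limma they had p = 0.00288 and p = 0.00231, ranks 5 and 2 of the 8344 genes tested, and neither passed adjustment over all of those genes (adjusted p = 0.999 for each). Limma and its intervals take 1 variance for both groups, while the SDs of these genes are larger in TAV. A permutation of labels also responds to unequal spread, and no test with unequal variances was run. Both genes were chosen because the study's group has written on them in these samples, so the single-gene tests are not independent evidence.

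**Figure D1:**
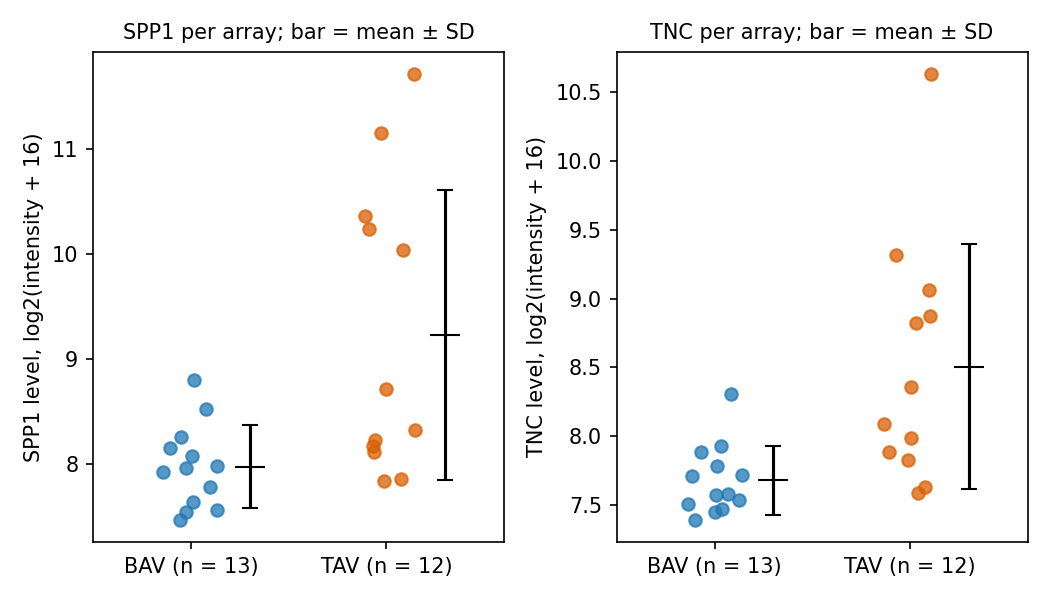
SPP1 and TNC levels in log2(intensity + 16) on the vertical axes, with 1 point per array for 13 BAV and 12 TAV arrays and bars for mean ± SD. The highest BAV array is at 8.80 for SPP1 and 8.31 for TNC, and TAV arrays reach 11.72 and 10.63.

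SPP1 and TNC belong to the list of matricellular proteins, secreted proteins that modulate how cells meet the matrix without forming its fibres. Of its 18 tested genes, 10 were lower in BAV and 8 higher, and 0 passed adjustment over all genes. Adjusted over the list alone, 2 passed, SPP1 and TNC, both with adjusted p = 0.0259, which is not independent evidence for the reason given. CCN5, a matricellular factor of smooth muscle, differed by 0.36 (p = 0.0852) and THBS2, thrombospondin 2, by -0.28 (p = 0.118). The list as a whole had a mean difference of -0.10 (-0.26 to 0.07) and a camera adjusted p = 0.213. In the list of osteochondrogenic and calcification genes, 1 of 17, SPP1, passed when adjusted over the list alone, and 0 over all genes, with a list mean of -0.07 and a median of 0.02 that differ in sign (camera adjusted p = 0.594). Over the other lists, adjustment over the list alone gave 0 genes in each of 43.

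Structural matrix genes showed mixed, smaller differences that did not pass. Among 17 collagen genes 10 were lower and 7 higher in BAV, with COL6A3 at -0.41 (p = 0.107), COL1A1 at -0.44 (p = 0.195), COL16A1 at 0.15 (p = 0.172) and COL6A1 at 0.16 (p = 0.218). The other probe sets of COL1A1 above the filter gave -0.06 and -0.03. The collagen list mean differed by -0.08 (-0.31 to 0.14). Of 21 genes of elastic fibres and their microfibrils 13 were higher and 8 lower, including ELN, the elastin gene, at 0.18 (p = 0.247), LTBP4, which helps elastic fibres assemble, at 0.34 (p = 0.0968) and MFAP3 at -0.12 (p = 0.0778). That list mean differed by 0.05 (-0.09 to 0.19). Among 20 proteoglycan genes, SRGN, the serglycin of blood cell granules, was at -0.34 (p = 0.0997), LUM, lumican, at -0.33 (p = 0.164) and PRELP at 0.28 (p = 0.187). Camera adjusted p values were 0.213 for collagens, 0.876 for elastic fibres and 0.621 for proteoglycans, whose mean (-0.01) and median (0.04) differ in sign.

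Markers of macrophages and monocytes were lower in BAV in all 20 tested genes, 8 of them with an unadjusted p under 0.05 and 0 past adjustment, over all genes or adjusted over the list alone. LAPTM5, a lysosomal protein of blood cells, differed by -0.60 (p = 0.0219), LYZ, lysozyme, by -0.59 (p = 0.0246), CD53, a leukocyte tetraspanin, by -0.48 (p = 0.025) and FCER1G, an Fc receptor chain, by -0.28 (p = 0.0279). The list mean was 8.51 ± 0.30 in BAV and 8.85 ± 0.51 in TAV, a difference of -0.33 (-0.67 to 0.007), with 11 of 13 BAV arrays below the TAV mean. Here and below, counts of BAV arrays past the TAV mean do not measure separation, since TAV arrays themselves lie on both sides of it. Camera with its preset correlation gave an adjusted p = 6.83e-16. That p overstates the evidence, since the correlation estimated for this list was 0.73 against the preset 0.01. The list was also called in many splits with shuffled labels. With an estimated correlation the p was 0.0237 (adjusted p = 0.401), and the permutation test of the list mean gave p = 0.0538 (adjusted p = 0.636).

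Lists of B cells and plasma cells, MHC class II and antigen presentation, T cells and NK cells, and neutrophils also had lower means in BAV, though none passed with an estimated correlation. Mast cell markers (mean difference 0.0005, -0.10 to 0.10, median -0.01, 3 of 8 genes higher) and erythrocyte and platelet markers (0.03, -0.18 to 0.25, 6 of 9 genes higher) did not, with camera adjusted p = 0.998 and 0.922. Of 18 B cell and plasma cell genes 16 were lower, by -1.80 for IGLC1 (p = 0.0198) and -0.999 for IGHM (p = 0.0507), which encode antibody chains, and by -0.54 for POU2AF1, a B cell transcription coactivator (p = 0.0526). The antibody probe sets can read several related genes. All 12 tested genes of the MHC class II and antigen presentation list were lower, with HLA-DRA at -0.47 (p = 0.073) and HLA-DPB1 at -0.43 (p = 0.0624). Of 22 T cell and NK genes 20 were lower, with CD4 at -0.14 (p = 0.0893) and IL7R at -0.29 (p = 0.131). Of 9 neutrophil genes 7 were lower, with FPR1, a receptor for bacterial peptides, at -0.30 (p = 0.0131) and FCGR3B at -0.24 (p = 0.0132).

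List means differed by -0.30 (-0.60 to 0.01) for B cells and plasma cells, -0.25 (-0.59 to 0.10) for MHC class II and antigen presentation, -0.08 (-0.23 to 0.06) for T cells and NK cells and -0.14 (-0.27 to -0.01) for neutrophils. They lay below the TAV mean in 12, 9, 12 and 11 of 13 BAV arrays. Camera with its preset correlation gave adjusted p = 6.70e-07, 1.20e-05, 3.95e-05 and 8.20e-05 in the same order, against adjusted p = 0.605, 0.603, 0.616 and 0.401 with an estimated correlation. No gene of these lists passed adjustment, over all genes or adjusted over the list alone (0 in each). TAV replicate 12 carried much of some of these means, and each of these lists had its smallest difference when that array was left out. The difference was then -0.20 for B cells and plasma cells and -0.13 for neutrophils. For macrophages and monocytes it was -0.24, again the smallest with 1 array left out. Without it the difference of MHC class II and antigen presentation was -0.14 and that of T cells and NK cells -0.04, and without TAV replicate 5 the latter was -0.05.

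The contractile apparatus of smooth muscle was higher in BAV in 23 of 24 tested genes. TPM1, a tropomyosin that runs along actin filaments, differed by 0.45 (p = 0.023), CALD1, caldesmon, by 0.40 (p = 0.0836), TPM2 by 0.38 (p = 0.129) and ACTA2 by 0.28 (p = 0.0962), and 0 genes passed adjustment, over all genes or adjusted over the list alone. The list mean was 10.72 ± 0.36 in BAV and 10.51 ± 0.51 in TAV, a difference of 0.21 (-0.15 to 0.57), with 11 of 13 BAV arrays above the TAV mean. Most TAV arrays lay above that mean too, since TAV replicates 1, 4 and 12, at 9.76, 9.80 and 9.84, lowered it. Camera gave an adjusted p = 8.20e-05 with its preset correlation and an adjusted p = 0.616 with an estimated correlation.

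Adipocyte markers, which report fat from the outer wall, were higher in BAV in all 11 tested genes, with GPD1 at 0.21 (p = 0.15), LEP, leptin, at 0.20 (p = 0.138) and LIPE, hormone-sensitive lipase, at 0.15 (p = 0.124). Their mean differed by 0.20 (-0.15 to 0.55), yet 6 of 13 BAV arrays lay above the TAV mean. It was 0.10 without BAV replicate 4 and 0.12 without BAV replicate 5. Camera gave an adjusted p = 0.000442, against an adjusted p = 0.616 with an estimated correlation, and 0 genes passed adjustment, over all genes or adjusted over the list alone.

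Lists of inflammatory signalling and proteolysis had more genes lower than higher in BAV, and none of these lists passed with an estimated correlation (adjusted p from 0.401 to 0.636). Of 13 NF-kB targets 12 were lower in BAV, with CCL2, a monocyte attractant, at -0.31 (p = 0.0352) and TRAF1 at -0.13 (p = 0.0446). Of 20 cytokines and chemokines 16 were lower, including SPP1 and CCL19, a lymphocyte attractant, at -0.38 (p = 0.0846). Of 26 interferon response genes 21 were lower, with MX2 at -0.20 (p = 0.0699) and ISG20 at -0.26 (p = 0.0618). Of 26 matrix proteases and inhibitors 20 were lower, with the lysosomal protease CTSS at -0.24 (p = 0.0171), PLAUR, the urokinase receptor, at -0.23 (p = 0.0382) and MMP9, a gelatinase, at -0.43 (p = 0.0701). The other probe sets of PLAUR gave -0.05 and -0.03.

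Mean differences were -0.10 (-0.22 to 0.02) for NF-kB targets, -0.15 (-0.33 to 0.02) for cytokines and chemokines, -0.08 (-0.25 to 0.09) for interferon response genes and -0.10 (-0.22 to 0.02) for proteases. The lists lay below the TAV mean in 9, 9, 10 and 10 of 13 BAV arrays, in that order. Camera gave adjusted p = 0.000112, 0.00168, 0.000161 and 0.000301, against adjusted p = 0.401, 0.608, 0.636 and 0.401 with an estimated correlation. No gene of these lists passed adjustment, over all genes or adjusted over the list alone (0 in each). The cytokine list holds SPP1, so it is not independent evidence, and with genes that stand in other lists removed its mean difference was -0.07 with an adjusted p = 0.15. Without TAV replicate 1 its adjusted p was 0.0628, and without TAV replicate 12 the interferon difference was -0.02 with an adjusted p = 0.131.

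Metallothioneins, which bind zinc and copper, were lower in BAV in 7 of 8 genes, with MT2A at -0.42 (p = 0.114) and MT1G at -0.27 (p = 0.0854), and MT3 was at 0.06 (p = 0.0738). The genes of hypoxia and glycolysis were lower in 21 of 32, with GAPDH at -0.24 (p = 0.0264) and HIF1A, the oxygen-regulated transcription factor, at -0.35 (p = 0.0921). Their means differed by -0.20 (-0.51 to 0.11) and -0.05 (-0.17 to 0.07), each below the TAV mean in 10 of 13 BAV arrays. Camera gave adjusted p = 0.00482 and 0.00544, against an adjusted p = 0.616 for each with an estimated correlation, and 0 genes of either list passed adjustment, over all genes or adjusted over the list alone. The metallothionein adjusted p was 0.051 without BAV replicate 8 and 0.101 without TAV replicate 9. For hypoxia and glycolysis it was 0.121 without TAV replicate 4 (difference -0.02) and 0.116 without TAV replicate 8 (difference -0.02), and without TAV replicate 1 the difference was -0.08.

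Lists of 4 developmental signalling pathways gave mean differences whose intervals include 0. Wnt signalling differed by 0.07 (-0.02 to 0.17), with 13 of 22 genes higher in BAV and a camera adjusted p = 0.347, and Hedgehog signalling by 0.05 (-0.03 to 0.13), with 4 of 6 genes higher and an adjusted p = 0.505. Of 18 Notch pathway genes 11 were higher in BAV and 7 lower, with the target HES1 at 0.18 (p = 0.0767), MAML1, a coactivator, at -0.05 (p = 0.246) and NCSTN, a secretase subunit, at -0.04 (p = 0.277). The Notch mean differed by 0.02 (-0.03 to 0.06). Of 30 TGF-beta and BMP genes 18 were higher and 12 lower, with BMP6 at -0.07 (p = 0.0308), ENG, endoglin, at -0.23 (p = 0.102), INHBB at -0.16 (p = 0.109) and BMP4 at 0.09 (p = 0.127). Their mean differed by 0.003 (-0.11 to 0.11). For Notch and for TGF-beta and BMP the camera adjusted p values were 0.87 and 0.71, with a direction opposite to the mean and the median in both lists. The median difference over all genes tested was 0.009.

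**Figure D2:**
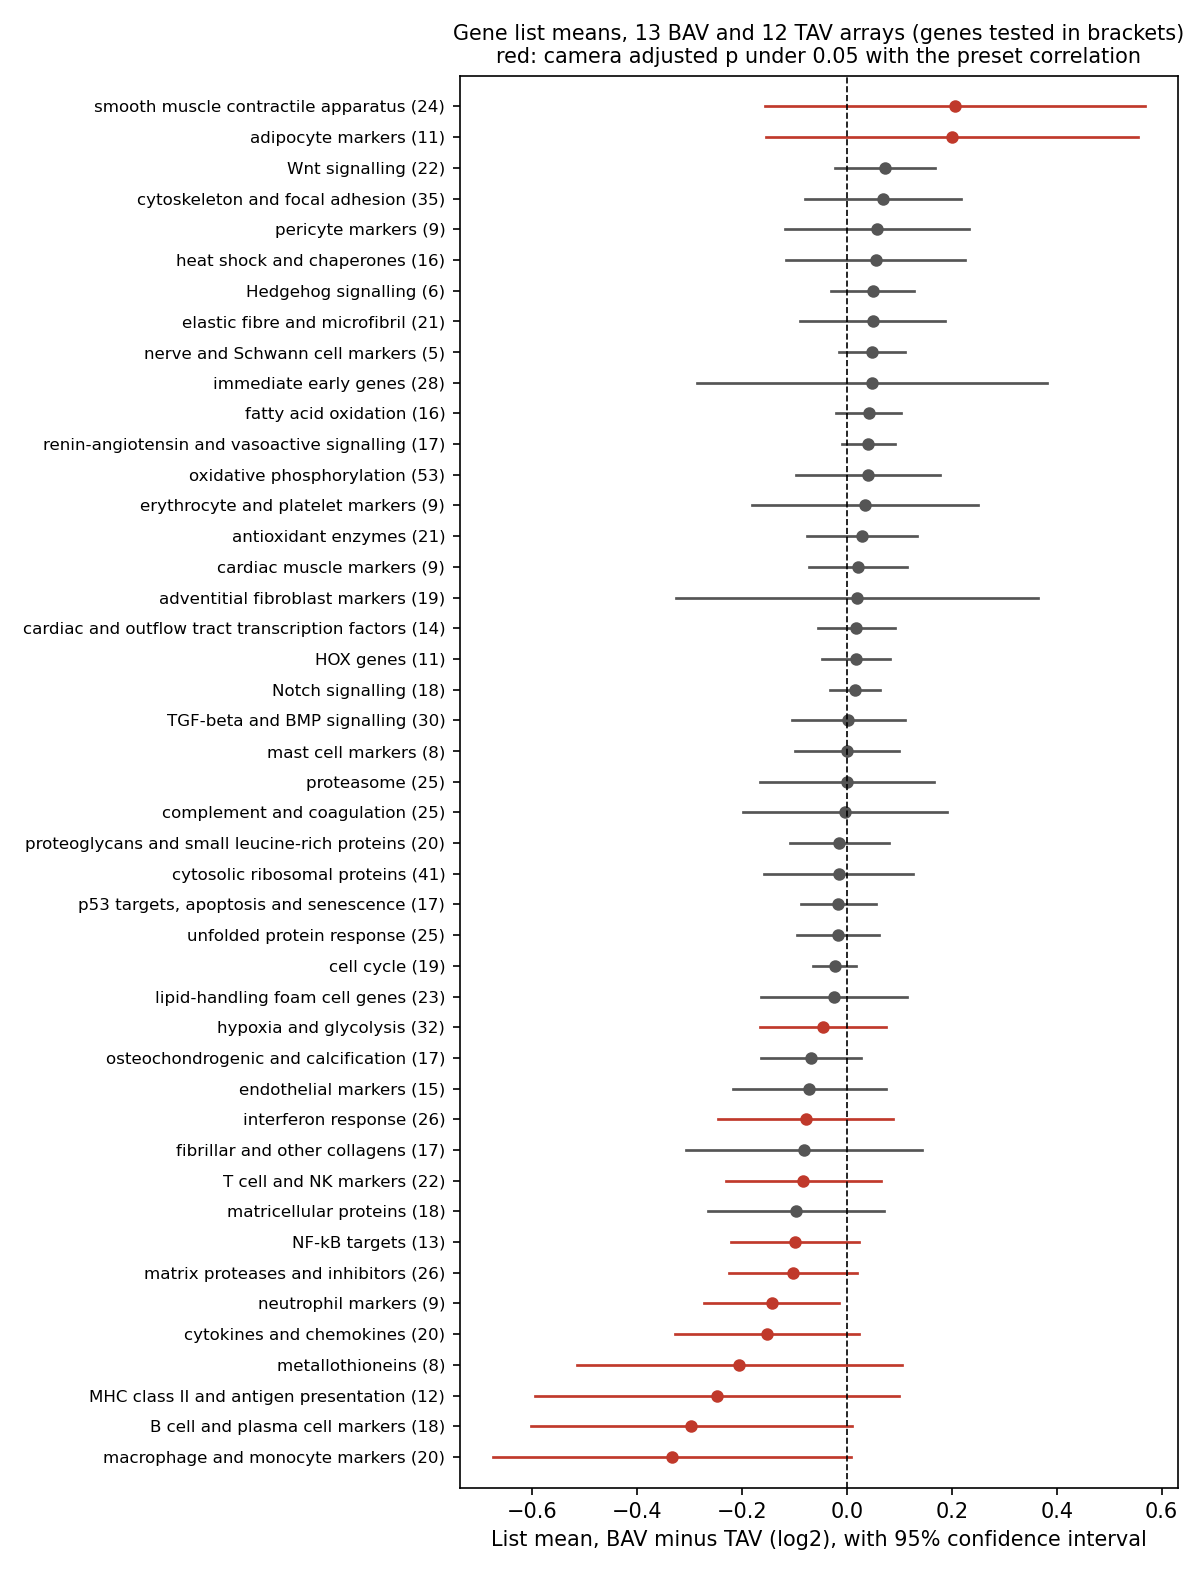
Mean log2 difference, BAV minus TAV, of each of the 45 tested gene lists on the horizontal axis, with 95% confidence intervals over 13 BAV and 12 TAV arrays and the number of tested genes in brackets. Red marks lists with a camera adjusted p under 0.05 at the preset correlation, and the interval excludes 0 for 1 list, neutrophil markers.

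Across the 45 lists, camera with the preset correlation called 2 lists higher in BAV and 11 lower. All of the 11 but hypoxia and glycolysis had their smallest difference, with 1 array left out, without TAV replicate 12. Agreement among these lists therefore rests in part on 1 patient. With an estimated correlation 0 lists passed (4 had an unadjusted p under 0.05), fry called 0 (smallest adjusted p = 0.735), and the permutation test of list means called 0 (1 list with an unadjusted p under 0.05, smallest adjusted p = 0.636). The count of lists higher in BAV was 4 without each of BAV replicates 1, 8 and 9 and TAV replicates 6, 7, 8 and 10, and 5 without TAV replicate 11.

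Gene by gene, the smallest p among genes higher in BAV belonged to AAMDC, at 0.27 (0.13 to 0.41, p = 0.000581) and above the TAV mean in 13 of 13 BAV arrays. Its other probe set above the filter gave 0.11, and a dimmer one below the filter gave 0.004. AAMDC was followed by VAT1, a vesicle membrane protein, at 0.18 (p = 0.00285) and SLC4A3, an anion exchanger, at 0.12 (p = 0.00328). INAVA, PTPRH, CTSF, ME3, ATP8B1, EEF1A1, TNFRSF8 and MMP15 were also among the 12 of smallest p, with differences from 0.09 to 0.28. The probe sets of VAT1, CTSF, ATP8B1, EEF1A1 and MMP15 carry a suffix that marks possible cross-hybridization.

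Among genes lower in BAV, TNC and SPP1 stood with ZC3H4 at -0.15 (p = 0.00255), YIPF1 at -0.10 (p = 0.00369), INTS6, a subunit of the Integrator complex, at -0.17 (p = 0.00584), PNP, a purine salvage enzyme, at -0.20 (p = 0.00595) and SET at -0.24 (p = 0.0062). ENTPD1, the ectonucleotidase CD39 of leukocytes and endothelium, was at -0.19 (p = 0.00677) and IGLL5, an immunoglobulin lambda-like gene, at -0.49 (p = 0.00731). CDC42SE1, the autophagy gene ATG7 and SLA, an adaptor of lymphocyte signalling, followed at -0.18, -0.08 and -0.17. The same suffixes mark the probe sets of SPP1, YIPF1, PNP, SET, IGLL5, CDC42SE1 and ATG7. Each of the genes named here by smallest p had an adjusted p = 0.999 and none passed.

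In limma 0 genes were higher and 0 lower in BAV at an adjusted p of 0.05, with a smallest adjusted p of 0.999. An unadjusted p under 0.05 was found for 206 genes, 91 higher and 115 lower, where 417 would be expected of independent genes without a difference. A linear model without moderation and a rank-sum test also called 0 genes, with 216 and 202 at an unadjusted p under 0.05. A difference of at least 1.5-fold was seen for 11 genes, 1 higher in BAV and 10 lower. The 206 became 133 without BAV replicate 1, 319 without BAV replicate 9, 443 without TAV replicate 1, 318 without TAV replicate 3 and 107 without TAV replicate 12.

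Across the 25 arrays, tissue with more macrophage transcript had less contractile transcript. The list means correlated with r = -0.66 (permutation p = 0.00038, adjusted p = 0.0019) and Spearman's rank correlation = -0.61 (p = 0.00166, adjusted p = 0.00422), with r = -0.70 without the 2 arrays farthest from the median on the contractile measure. Within groups r was -0.77 over 13 BAV arrays and -0.58 over 12 TAV arrays. BAV replicates 4 and 9 had the lowest contractile means in BAV (9.98 and 9.96) and the highest macrophage means (8.92 and 9.07). The r within BAV without them was not computed, and the 2 arrays left out above were TAV replicates 1 and 4. Contractile means also went down as T cell and NK means went up (r = -0.64, permutation p = 0.00109, adjusted p = 0.00272, and Spearman correlation = -0.64, p = 0.00054, adjusted p = 0.0027) and as B cell and plasma cell means did (r = -0.59, p = 0.00264, adjusted p = 0.00528, and Spearman correlation = -0.61, p = 0.00169, adjusted p = 0.00422). Without the 2 farthest arrays these r were -0.69 and -0.66. Within BAV they were -0.33 and -0.38, and within TAV -0.72 and -0.63. With collagens the contractile mean had r = -0.05 (p = 0.806, adjusted p = 0.806) and Spearman correlation = 0.22 (p = 0.292, adjusted p = 0.364), with r = 0.19 without the 2 farthest arrays.

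SPP1 followed the macrophage mean, with r = 0.81 (permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 1e-04) and Spearman correlation = 0.70 (p = 0.00018, adjusted p = 0.0018). Without the 2 arrays farthest from the macrophage median r was 0.61, and within groups it was 0.58 in BAV and 0.85 in TAV. TNC followed it less closely, with r = 0.57 (p = 0.00542, adjusted p = 0.00903), Spearman correlation = 0.43 (p = 0.0313, adjusted p = 0.0448), r = 0.49 without the 2 farthest arrays, and r = 0.34 in BAV and 0.50 in TAV. SPP1 and TNC correlated with r = 0.70 (p = 0.00067, adjusted p = 0.00223) and Spearman correlation = 0.57 (p = 0.00342, adjusted p = 0.00684), with r = 0.70 without the 2 arrays farthest in SPP1, 0.43 within BAV and 0.58 within TAV. These belong to a family of 10 relations, whose permutations shuffled all arrays without regard to valve group. SPP1, TNC and the macrophage mean were all lower in BAV, so the difference between groups enters their r and p over all arrays. The r within groups were not tested. The contractile mean had r = -0.51 with MHC class II and antigen presentation (permutation p = 0.0082, adjusted p = 0.0117). With adipocyte markers it had r = -0.15 (p = 0.484, adjusted p = 0.605). Macrophage and collagen means had r = 0.10 (p = 0.609, adjusted p = 0.677).

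**Figure D3:**
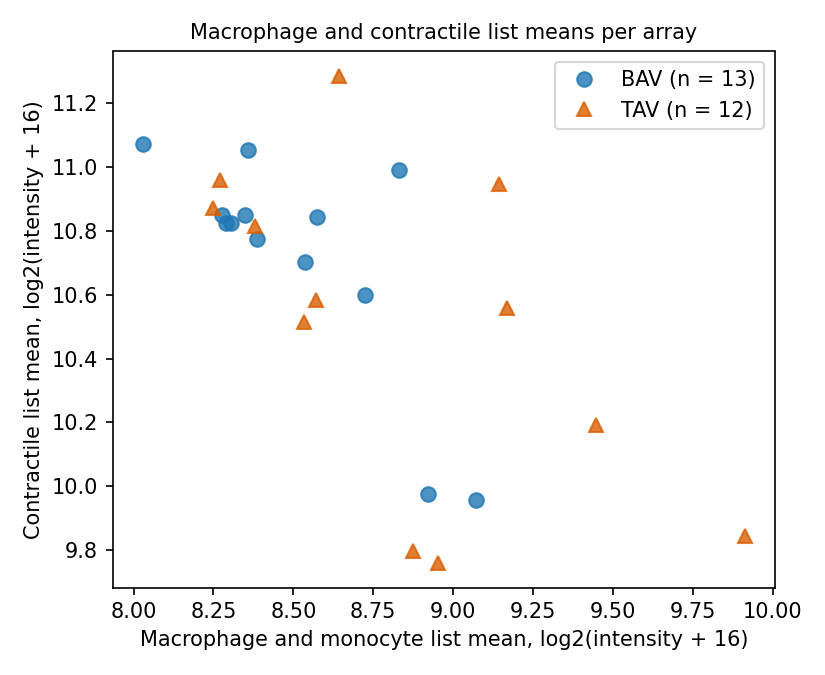
Macrophage and monocyte list mean on the horizontal axis against the smooth muscle contractile list mean on the vertical axis, both in log2(intensity + 16), with 1 point per array for 13 BAV and 12 TAV arrays. The points run downward, with r = -0.66 over the 25 arrays.

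No array measure passed a permutation test between the groups. Array medians were at 7.86 in BAV and 7.85 in TAV (permutation p = 0.37, adjusted p = 0.53), and 75th percentiles at 8.30 and 8.31 (p = 0.424, adjusted p = 0.53). Principal component 1, with 43.5% of the variance, ran from immunoglobulin, C1QB and CD74 transcripts to SYNM, LTBP1 and SPARCL1 and differed by 3.41 between groups (p = 0.544, adjusted p = 0.544). UCP2 and RPS15 also stood at its first end. Its farthest arrays, TAV replicates 1, 3 and 11 and BAV replicate 8, were the 4 with a limma weight under 0.5. TAV replicates 1 and 3 and BAV replicate 8 (-33.9, -21.0 and -23.2) had array medians of 7.90, 7.89 and 7.89. TAV replicate 11 (19.8) had 7.81, while BAV replicate 1, with 7.90, stood at -2.51. Whether this component is technical was not tested. Principal component 2, with 14.9%, ran from MYL9, TAGLN and LMOD1 of contractile smooth muscle to SPP1, TNC, CD163 and CD14, and differed by -5.16 (p = 0.109, adjusted p = 0.513). Principal component 3, with 7.32%, ran from FOSB, FOS and the fat genes ADIPOQ and FABP4 to SPP1, IGHM and MMP9, and differed by -2.90 (p = 0.205, adjusted p = 0.513).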

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

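The settings chosen only after the data were seen were background subtraction, the removal of low-weight arrays and principal component 1 as a covariate. Genes past adjusted p 0.05 numbered 0 in each direction under every alternative tried. SPP1 kept its direction over 40 settings, from -1.75 (2nd percentile subtracted) to -0.98 (array weights), with unadjusted p from 0.00125 to 0.00663 and a lowest adjusted p of 0.526, and TNC from -1.40 to -0.44 (its other probe set) with unadjusted p from 0.000392 to 0.00515. With 1 array left out SPP1 ran from -1.38 to -1.03 and TNC from -0.91 to -0.63. Lists higher in BAV numbered 4 after quantile normalization. With an estimated correlation, with fry and with the permutation test of list means, 0 lists were higher and 0 lower. The first still compares a list with other genes, while fry and the permutation test do not. Lists lower in BAV numbered 17 without the 4 arrays of weight under 0.5, which were 1 BAV and 3 TAV arrays. With 1 array left out the counts ran from 2 to 5 higher and from 10 to 14 lower. Genes with an unadjusted p under 0.05 numbered 381 with no filter and 324 over all probe sets, where more features were tested, 643 with array weights, 595 without low-weight arrays and 782 with principal component 1 as a covariate, and from 107 to 443 with 1 array left out. The cause of the other changes was not tested. MFNG was at -0.07 and reversed to 0.0045 as a mean of its probe sets. Named genes besides SPP1 and TNC gave 3561 fits with the same sign, which speaks for sign alone, since none of these genes passed in the main fit and no call could be lost. The 13 lists gave 470 fits with the same sign and call, 49 weaker and 0 reversed. Among the weaker, the adipocyte list had an adjusted p of 0.192 with array weights, and the interferon and cytokine lists 0.0989 and 0.11 with principal component 1 as a covariate. TNC fell below the filter as a mean of its probe sets, and control probe ratios were not run for want of control probe sets in the table used here. Medians and 75th percentiles are fixed by quantile normalization. A background level remains in the intensities, so signal over background limits what can be seen for dim genes.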

Other observations

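Measured SPP1 and TNC levels were more spread among TAV than among BAV arrays. The SD among TAV arrays was 3.52 times that among BAV arrays for SPP1 (permutation p = 2e-05, adjusted p = 0.00094 over 47 items) and 3.53 times for TNC (p = 0.0008, adjusted p = 0.0188). The 47 items are the 45 list means with SPP1 and TNC, not all genes tested. Both genes were chosen because the study's group has written on them in these samples. High TAV arrays that raise their TAV means also widen their TAV spread, so these p values are not independent evidence. BAV means of 7.98 and 7.68 lie close to or below the filter of 7.73, where background left in the values compresses the spread, so these ratios are not a plain comparison of patient-to-patient variation. With 1 array left out the ratio ran from 3.04 to 4.32 for SPP1 and from 2.42 to 5.08 for TNC. B cell and plasma cell means were 2.96 times as variable in TAV (p = 0.00398, adjusted p = 0.0624) and T cell and NK means 2.92 times (p = 0.00628, adjusted p = 0.0738), and neither passed adjustment. Of the 45 lists 34 had the wider spread in TAV, and the 1 list with the wider spread in BAV at an unadjusted p under 0.05 was lipid-handling foam cell genes, with a ratio of 0.576 (p = 0.027, adjusted p = 0.254). Adipocyte markers had a ratio of 0.416 (p = 0.0564, adjusted p = 0.293).

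An antibody probe set gave the highest intensity on TAV replicates 1, 10 and 12, though intensities of different probe sets do not rank transcript amounts. The brightest probe sets of BAV replicate 5 and TAV replicates 3 and 5 had no single gene symbol and were not named. IGLC1, an immunoglobulin lambda chain gene, was at 9.97 ± 1.35 (SD, n = 13) in BAV and 11.77 ± 2.36 (n = 12) in TAV, and on TAV replicate 1 its intensity of 35085 was the highest in the table. That array also had the lowest limma weight, 0.18, and the lowest mean correlation with the other arrays, 0.87. These values and the spreads above were chosen for description after they were seen.

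The counts of splits that gave as many lists or genes, and the left-out arrays and lists for the gap between cell types, were chosen only after the results were seen. The lower SPP1 and TNC in BAV passed a permutation test singly but not adjustment over all genes. With the macrophage list mean as a covariate the difference was -0.63 (-1.17 to -0.08, p = 0.0266) for SPP1, 49.9% of the unadjusted one. For TNC it was -0.59 (-1.08 to -0.09, p = 0.0215), 71.2% of the unadjusted one. Both intervals exclude 0, against what was predicted if macrophage content were the whole cause. That does not settle the question, since a list mean measures macrophage content with error. Adjusting for it can leave a difference that macrophages cause. A single outlying array is argued against, since the highest unadjusted p with 1 array left out was 0.00623 for SPP1 and 0.00515 for TNC. Macrophage content in part or in whole, a technical batch that the labels used here do not give, and the valve type itself stay open, the last as a hypothesis on genes that were not chosen independently of these samples.

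Immune lists other than mast cell markers (0.0005) had lower means in BAV, and camera with its preset correlation called 13 lists in all, against 0 with an estimated correlation (smallest adjusted p = 0.401), fry or permutation. Chance cannot be excluded for that count, since 46 of 100 splits of the arrays, the real one included, called as many lists, with 24 in the highest other split. A lower share of smooth muscle in TAV, which would raise every other cell type alike, stays open. The mean shift of endothelial (-0.07), adventitial fibroblast (0.02), adipocyte (0.20) and nerve (0.05) lists was set against that of the macrophage, B cell, T cell and neutrophil lists. It exceeded theirs by 0.26 (0.01 to 0.52), but the interval barely clears 0. Mast cell markers (0.0005) and MHC class II (-0.25) were not in the immune mean. The first would lower the gap, the second would raise it, and no fit with either was run. The interval included 0 in 10 of the 25 fits with 1 array left out, with the lowest gap of 0.19 (-0.03 to 0.40) without TAV replicate 12. It also did in 2 of the 4 fits with 1 list left out, adipocyte (0.21, -0.01 to 0.44) or nerve. More immune cells in some TAV walls may be present, as a hypothesis, but list means per patient did not pass adjustment.

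The count of genes with an unadjusted p under 0.05, at 206, was lower than independent genes would give. Genes that vary together from patient to patient are a candidate explanation, since 52 of 100 splits gave as small a count and the middle of the other counts ran from 29 to 2392, with a median of 195. Chance cannot be excluded as the source of the 206 (49 of 100 splits gave as many, 3195 in the highest other split). For the 0 genes past adjusted p 0.05 the splits decide nothing, since all 100 of 100 must give at least 0, and the highest other split gave 171. Splits with many times the real count point to a structure of the samples that the valve groups do not follow, and no biological or technical explanation was tested for it.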
